A study of Mus musculus with 8 samples.

How the data were processed

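RNA was measured by sequencing in NKT cells from the thymus of C57BL/6 mice, 4 WT and 4 Ezh2-KO samples in 3 subsets. Per the labels' protocols, RNA was extracted with the RNeasy Plus Mini Kit and libraries were made with a TruSeq RNA kit. Each library was sequenced on 4 lanes per the labels. The replicates of CD44+ NK1.1- cells are biological per the series design text. Whether the subsets came from the same animals is not stated, so libraries were treated as independent.

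The deposited values are raw read counts per gene, made by the authors and checked here to be whole numbers. Per the submitters' processing notes, reads were called with CASAVA, aligned to mouse build mm10 with Subread 1.4.3-p1 and counted per gene with featureCounts. The gene annotation behind the counts and the strand setting are not given in the sources used here. All 8 files of single libraries held the same counts as the table of the series, and every column was mapped to its library by the labels. The files hold 27179 gene identifiers, of which 25275 matched a gene symbol in a RefSeq table of the same assembly, the source of the positions printed here.

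Library depth ranged from 20308745 to 22995090 counts. A gene with no reads is therefore bounded at 3 counts, 0.129 to 0.151 CPM, and where a side of a comparison had 1 to 3 counts in all, the ratio of the counts is given with an interval for counting error.

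Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr on the 6 groups, which left 13794, of them 13398 with a symbol. Libraries were scaled by TMM. Spread was estimated with estimateDisp, models were fitted with glmQLFit (robust=TRUE) and tested with the quasi-likelihood F test of edgeR, and p-values were adjusted by Benjamini and Hochberg within a comparison. A gene counts as called at an adjusted p under 0.05. Adjusted p in the text is from edgeR unless another tool is named.

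The first model gave each of the 6 groups its mean and left 2 residual degrees of freedom, 1 from each replicated group (prior degrees of freedom 4.17, biological coefficient of variation 0.141). From it came Ezh2-KO against WT in each subset, the comparisons between subsets as the mean over both genotypes, and the differences of the genotype effect between subsets. The second model took subset and genotype as added effects over all 8 libraries and left 4 residual degrees of freedom (prior degrees of freedom 4.11, coefficient 0.137). It assumes that the genotype effect is alike in the 3 subsets.

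Lists of genes were tested with camera, which asks whether a list ranks higher or lower than other genes, at its preset correlation of 0.01 and with a correlation estimated from the same residuals. With so few residual degrees of freedom the estimate is poor. The test called fry asks instead whether the genes of a list move on balance in 1 direction, without regard to other genes. Adjustment ran over the 29 lists of a comparison. The lists were PRC2 genes, cell cycle inhibitors, developmental regulators, NKT transcription factors, NKT1, NKT2 and NKT17 genes, cytokines, NK receptors, immature thymocyte genes, proliferation, apoptosis, trafficking, T cell receptor activation, interferon response, glycolysis, cholesterol, chromatin modifiers, T cell receptor constant and coreceptor genes, markers of B, myeloid, dendritic, thymic epithelial, erythroid, NK or innate lymphoid, gamma-delta T and regulatory T cells, immediate early and heat shock genes. A sex-linked list, the last of 30, had 1 tested gene where 3 were needed, and was not tested. Medians of lists were also taken with genes at 0 to 3 counts on 1 side at the ratio of the counts, 0 being raised to 3, and are given where they differ. Lists overlap, so that Eomes, Klra4, Tbx21 and Sox13, among others, count in more than 1 of them, and many NK and gamma-delta markers are also expressed by NKT cells.

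Named genes follow a rule. Always named are Ezh2, Zbtb16, Tbx21, Gata3, Il4, Ifng, Il17a, Klrb1c, Cd44, Il2rb and Cdkn2a. To these come the 8 largest rises and falls among called genes, or 4 where a side has 1 library or for differences of effects, given a symbol, a mean of at least 4 log2 CPM in the higher group and no overlap between the libraries compared. From each list up to 4 genes with the smallest p may be named, and any member of a called list. Some genes that the rule names are not reported here and are not in the counts of named genes. Comparisons, models, lists, the naming rule and most alternatives were chosen before the data were examined.

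The alternatives were DESeq2 size factors or library size in place of TMM, no filter on low counts or at least 1 CPM in 2 libraries, the DESeq2 Wald test or limma-voom in place of edgeR, robust=FALSE, a test against a fold of 1.5 with glmTreat, each library left out in turn, only the 4 CD44+ NK1.1- libraries, the mean of the 3 genotype effects, and single genotypes for the subset comparisons. What is called WT or Ezh2-KO libraries alone is a contrast within the fit of all 8 libraries, with spread and scaling from both genotypes. Leaving 5 lists out of the test was added after the data were seen. Where a setting left a group with 1 library, that library was assumed to vary like the rest.

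The pipeline was tested on simulated data with 13794 genes, 200 of them changed. Apart from these changes each gene had 1 mean and 1 spread in all simulated libraries. In the data the WT pair lay further apart than the Ezh2-KO pair, so the rates found need not hold there. For CD44+ NK1.1- cells it found 23.9%, 68.7% and 87.9% of genes changed 1.5-fold, 2-fold and 4-fold, with 16 false among 136 calls, more than the nominal share. Over the 3 subsets it found 52.2%, 74.6% and 90.9%, with 11 false of 156. With 1 library per side 19 of 93 calls were false in CD44+ NK1.1+ cells and 27 of 102 in CD44- NK1.1- cells, where 0% of the 1.5-fold changes were found. False calls among all calls were 15 of 151 and 14 of 138 for the subset comparisons, and 19 of 79 and 5 of 55 for the differences of the genotype effect. A changed set gave a camera p of 1.32e-214 and a random set 0.549.

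Left out were splicing, allele and sequence questions, since only gene counts were used here, and the deleted part of Ezh2, which gene counts do not resolve.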

Results

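The data were RNA-seq read counts per gene in natural killer T (NKT) cells from the thymus of C57BL/6 mice. NKT cells are T cells whose receptor recognises lipids shown by CD1d. The 8 libraries came from 4 WT and 4 Ezh2-KO samples. Ezh2 encodes the enzyme of the Polycomb complex PRC2, which methylates histone H3 at genes kept silent. Cells were grouped by the surface proteins CD44 and NK1.1 into 3 subsets. CD44- NK1.1- cells are commonly placed earliest in thymic NKT development and CD44+ NK1.1+ cells last. CD44+ NK1.1- cells had 2 biological replicates per genotype, and each of the other 4 groups had 1 library and so no replicates.

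The total counts of WT CD44+ NK1.1- replicates 1 and 2 were 22184044 and 22995090. Those of Ezh2-KO CD44+ NK1.1- replicates 1 and 2 were 20308745 and 21259872. The CD44+ NK1.1+ libraries held 22335825 counts in WT and 21310367 in Ezh2-KO. The CD44- NK1.1- libraries held 22056219 counts in WT and 20839898 in Ezh2-KO. At these depths 3 counts, the limit for a gene with no reads, came to between 0.129 and 0.151 CPM, counts scaled by the size of the library. Intervals and limits given here cover counting error only. Levels are in CPM after TMM scaling, as mean ± SD of the 2 replicates of CD44+ NK1.1- cells and as the single value elsewhere, and changes are log2 fold changes with the standard error (SE) of the fit. Mapping positions are on mouse genome build mm10.

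The WT replicates lay further apart than the Ezh2-KO replicates. Of 9276 genes compared in the WT pair, 166 differed over 2-fold, against 3 of 9369 in the Ezh2-KO pair. Genes of the immediate early response, which cells switch on within minutes of a stimulus, summed to 4651 CPM in WT replicate 1 and 1054 CPM in WT replicate 2, against 995 and 927 CPM in the Ezh2-KO replicates. The share of counts in genes with mitochondrial symbols was 0.154% in WT replicate 1 and between 0.0387% and 0.0745% in the other 7 libraries.

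Ezh2 (gene identifier 14056, chromosome 6, 47530274 to 47595270) was lower in every Ezh2-KO library than in the WT library or libraries of its subset. In CD44+ NK1.1- cells it measured 125 ± 15.9 CPM in WT, from 113 and 136, and 80.6 ± 3.81 CPM in Ezh2-KO, from 83.3 and 77.9. CD44+ NK1.1+ cells had 57.1 CPM in WT and 40.4 in Ezh2-KO, and CD44- NK1.1- cells had 109 and 78.4. Reads over the gene therefore remained in all 4 Ezh2-KO libraries, and a count over the whole gene cannot show which part was deleted. The change was -0.63 (SE 0.12, adjusted p = 0.0407) in CD44+ NK1.1- cells. That call ended with scaling by library size (-0.58, adjusted p = 0.0523), when tested against a fold of 1.5 (adjusted p = 1) and without Ezh2-KO replicate 1 (adjusted p = 0.324) or 2 (adjusted p = 0.440). Over the 3 subsets the change was -0.56 (SE 0.07, adjusted p = 0.00402), a call kept without any single library but lost against a fold of 1.5. The single-library subsets gave -0.50 (adjusted p = 0.375) in CD44+ NK1.1+ and -0.47 (adjusted p = 0.473) in CD44- NK1.1- cells.

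**Figure D1:**
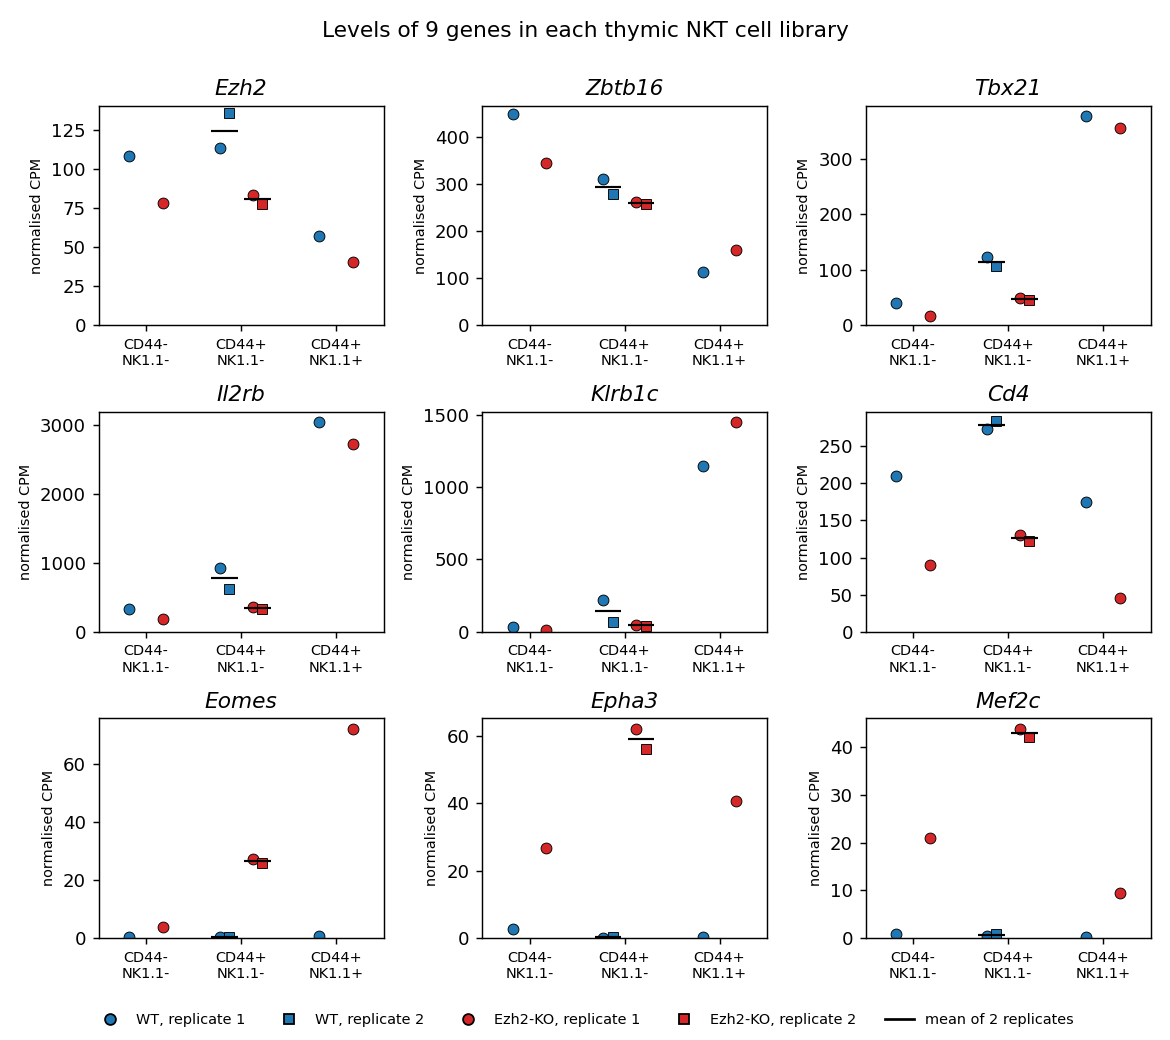
Normalised CPM (y axis, from 0) of 9 genes in the 3 subsets (x axis), with WT in blue and Ezh2-KO in red, circles for replicate 1, squares for replicate 2 and a black line at the mean of 2 replicates. Ezh2 and Cd4 were lower in Ezh2-KO in all 3 subsets, and Eomes, Epha3 and Mef2c were higher in all 3.

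Which genes change without Ezh2 in CD44+ NK1.1- cells was asked first, since this subset has replicates of both genotypes. Genes that WT cells hardly expressed rose furthest. Eomes, a transcription factor of natural killer (NK) cells and memory T cells (gene identifier 13813, chromosome 9, 118478186 to 118486132), went from 0.483 ± 0.0462 to 26.6 ± 0.867 CPM, a change of 5.76 (SE 0.18, adjusted p = 0.000200). The ephrin receptor gene Epha3 (gene identifier 13837, chromosome 16, 63543532 to 63864175) went from 0.327 ± 0.207 to 59.1 ± 4.17 CPM, a change of 7.46 (SE 0.29, adjusted p = 0.000236). Cd4, the coreceptor gene that part of NKT cells express (gene identifier 12504, chromosome 6, 124864693 to 124888247), fell from 279 ± 7.25 to 126 ± 5.84 CPM, a change of -1.14 (SE 0.09, adjusted p = 0.00320). Tbx21, which encodes T-bet, the factor of interferon-gamma producing NKT1 cells (gene identifier 57765, chromosome 11, 97098007 to 97115331), fell from 115 ± 11.8 to 47.2 ± 2.05 CPM, a change of -1.29 (SE 0.11, adjusted p = 0.00342).

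Mef2c, a MADS-box transcription factor gene (gene identifier 17260, chromosome 13, 83504017 to 83667079), rose from 0.698 ± 0.3502 to 42.9 ± 1.21 CPM (change 5.92, adjusted p = 0.000514). Grb10, a signalling adaptor gene (gene identifier 14783, chromosome 11, 11930499 to 12037428), rose from 0.265 ± 0.0711 to 28.7 ± 2.39 CPM (change 6.73, adjusted p = 0.000229). The transcription factor gene Tcf24 (gene identifier 100039596, chromosome 1, 9960163 to 9967981) had 1 count in the WT pair and 750 in the Ezh2-KO pair, a ratio of 789 with a counting interval of 141 to 31210 (adjusted p = 0.000781). Nrn1, Neo1 and Wwc1, which encode a neuritin, a netrin receptor and a scaffold protein, rose by 5.50, 4.68 and 4.15, with adjusted p between 0.000200 and 0.000811. Those were the 8 largest rises by the naming rule. The largest fall was in 9530036M11Rik, a long non-coding RNA gene (gene identifier 78616, chromosome 6, 54137935 to 54152446), from 47.2 ± 1.94 to 6.60 ± 0.972 CPM (change -2.83, adjusted p = 0.000781). Whether the counting kept to 1 strand is not stated, so reads of an overlapping transcript cannot be set apart there. Dtx1, a target of Notch signalling (gene identifier 14357, chromosome 5, 120680203 to 120711867), fell from 43.3 ± 2.48 to 9.99 ± 0.576 CPM (change -2.11, adjusted p = 0.000925). Emilin1 (-2.28), Igsf23 (-1.94), Cd7 (-1.74), Tm6sf1 (-1.71), the transporter gene Slc22a3 (-1.68) and the myosin gene Myo1f (-1.56) made up the other falls, with adjusted p between 0.00320 and 0.0391. Cd7, Tm6sf1, Myo1f and Tbx21 were high in CD44+ NK1.1+ cells, with 20204, 1356, 11680 and 7839 counts in WT and 16678, 1099, 11113 and 7076 in Ezh2-KO. Igsf23 and Dtx1 fell more there, from 1565 to 226 and from 1789 to 955. For the former genes a change within cells cannot be told apart from an unlike share of NK1.1+ or similar cells in the sorted subset.

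Among 13794 tested genes, 682 differed in CD44+ NK1.1- cells, 522 higher and 160 lower in Ezh2-KO, and 2853 had an unadjusted p under 0.05. The higher genes had a median WT level of 2.04 CPM, and 202 of them (38.7%) lay below 1 CPM in WT, against 14.5% of all tested genes. The lower genes had a median WT level of 55.6 CPM. Part of this contrast is built in, since the WT level is the base of the fold change. A gene barely expressed in WT can hardly be called lower, and it passes the filter through its level in another group. Called genes over 2-fold different numbered 426 higher and 61 lower. The count depended on single libraries, with 101 calls without Ezh2-KO replicate 1, 108 without Ezh2-KO replicate 2, 3751 without WT replicate 1 and 5792 without WT replicate 2. Of the 49 named genes called here, 12 kept their call without Ezh2-KO replicate 1 and 12 without replicate 2, and all 49 kept it without either WT replicate. Tcf24, Epha3, Grb10, Mef2c, Eomes, Nrn1, Neo1, Wwc1, 9530036M11Rik, Dtx1 and Sox13 kept it in every setting tried, whereas the adjusted p of Tbx21 was 0.0548 and 0.0607 and that of Cd4 reached 0.0655 with 1 Ezh2-KO replicate left out. The split also depended on single libraries, as 50.4% of calls were higher without WT replicate 1 and 50.1% without WT replicate 2, but 95.05% and 97.2% without Ezh2-KO replicates 1 and 2. DESeq2 called 653 genes, 383 higher and 270 lower, of which 483 were shared.

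Regulators and cytokines that define NKT lineages were followed by name. Il2rb, the interleukin-2 receptor beta chain gene, fell by 1.16 on the log2 scale (adjusted p = 0.0303), and Cd44, whose protein was used to define the subset, fell by 0.62 (adjusted p = 0.0436). Of the other regulators, Zbtb16, which encodes the NKT factor PLZF, measured 294 ± 22.4 CPM in WT and 259 ± 3.26 in Ezh2-KO (change -0.18, adjusted p = 0.360). Gata3, the factor of NKT2 cells, differed by -0.22 (adjusted p = 0.278). For the cytokine genes the values were -0.28 (adjusted p = 0.252) for Il4, -4.32 (adjusted p = 0.325) for Ifng and -1.67 (adjusted p = 0.606) for Il17a. Ifng stood at 36.8 CPM in WT replicate 1 and 3.27 in WT replicate 2, and Il17a at 4.19 and 0.129. Klrb1c, which encodes the gated protein NK1.1, stood at 217 and 68.5 CPM in these WT replicates and differed by -1.64 (adjusted p = 0.340). Cdkn2a, a cell cycle inhibitor gene held silent by PRC2 in many tissues, differed by -0.02 (adjusted p = 0.965) and had levels of 4.99 ± 0.238 CPM in WT and 4.92 ± 0.399 in Ezh2-KO. Without an Ezh2-KO replicate the call of Il2rb ended (adjusted p up to 0.222), as did that of Cd44 (up to 0.427), and Il17a was called higher without WT replicate 1 (2.33, adjusted p = 0.0286).

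Genes of NKT1 cells were lower as a list in Ezh2-KO CD44+ NK1.1- cells. Of 28 tested, 0 rose and 4 fell, against 1 and 8 adjusted over the list alone. Their median change was -1.15 (camera adjusted p = 4.20e-08, and adjusted p = 0.895 with an estimated correlation). The called members were Tbx21, Id2 (-0.49, adjusted p = 0.0353), Il2rb and the chemokine receptor gene Cxcr3 (-0.70, adjusted p = 0.0121). NKT1 genes summed to 4052 CPM in WT replicate 1 and 2628 in WT replicate 2, against 1849 and 1808 in the Ezh2-KO replicates. Without WT replicate 1 the list's median was -0.54 (adjusted p = 1.16e-08), and without WT replicate 2 it was -1.45.

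Gamma-delta T cell markers were higher as a list, these cells being a T cell lineage with another receptor. Sox13, a factor of gamma-delta and interleukin-17 producing T cells, rose from 59.3 ± 3.53 to 158 ± 3.73 CPM (change 1.41, adjusted p = 0.00163). The receptor constant genes Trdc (2.03, adjusted p = 0.00855) and Trgc1 (0.67, adjusted p = 0.0173), the variable gene Trgv6 (1.196, adjusted p = 0.0413) and 5830411N06Rik (0.90, adjusted p = 0.00731) also rose. Of 11 tested genes 5 rose and 0 fell, or 8 and 0 adjusted over the list alone. The median was 0.66 (camera adjusted p = 2.86e-05, and adjusted p = 0.861 with an estimated correlation). Reads can be shared among paralogous receptor segments, which leaves their single values uncertain. Without Ezh2-KO replicate 1 or 2 only 1 gene of the list stayed called in each case, Sox13, while the list's adjusted p stayed at or below 0.000144.

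Trafficking genes, the chemokine receptors and adhesion molecules that guide cells, moved both ways. The chemokine receptor genes Ccr6 (-1.94, adjusted p = 0.0186), Cx3cr1 (-1.72, adjusted p = 0.00618) and Ccr8 (-1.13, adjusted p = 0.00405) fell together with the integrin gene Itgae (-1.23, adjusted p = 0.0161), Cxcr3 and Cd44, while the integrin genes Itga4 (0.87, adjusted p = 0.00906) and Itgb1 (0.83, adjusted p = 0.0137) rose. That made 2 higher and 6 lower among 29 tested, or 4 and 11 adjusted over the list alone. The list's median was -0.29 (camera adjusted p = 0.0292, and adjusted p = 0.861 with an estimated correlation), and its call ended without Ezh2-KO replicate 2 (adjusted p = 0.0709). Immediate early genes were lower as a list, with a median of -2.05 (camera adjusted p = 0.00563, and adjusted p = 0.895 with an estimated correlation). Only Egr1 (-0.54, adjusted p = 0.0355) of 16 tested was called, over all genes and adjusted over the list alone. Without WT replicate 1, where the list stood highest, the median was 0.13 (adjusted p = 0.416), and without WT replicate 2 it was -2.92 (adjusted p = 1.31e-114).

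Natural killer receptor genes and NK or innate lymphoid markers were not called as lists here. The receptor genes Klra4 (2.18, adjusted p = 0.00725) and Klrb1b (0.67, adjusted p = 0.0438) rose, and 0 of 33 tested fell, the counts adjusted over the list alone being the same (median -0.56, adjusted p = 0.446). Without WT replicate 1 these receptor genes were called higher as a list (median 0.39, adjusted p = 4.10e-06), and without WT replicate 2 lower (median -0.99, adjusted p = 4.52e-10). They summed to 1143 CPM in WT replicate 1 and 512 in WT replicate 2, against 766 and 729 in Ezh2-KO. Reads may be shared within the Klra family. Klra4 and Eomes rose among 10 NK or innate lymphoid markers, 3 higher and 1 lower adjusted over the list alone. That list's median (-0.90) and mean (0.18) differed in sign, with the test on the side of a rise (adjusted p = 0.446). It summed to 541 CPM in WT replicate 1, 139 in WT replicate 2 and 160 and 162 in Ezh2-KO, and it was called higher without WT replicate 1 (adjusted p = 0.00122) or Ezh2-KO replicate 1 (0.0424) and lower without WT replicate 2 (0.0282).

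Other NKT lists were uncalled with called members. NKT transcription factors had Lef1 (1.04, adjusted p = 0.0121) and Eomes higher and Tbx21, Id2, Egr1 and Runx3 (-0.86, adjusted p = 0.0247) lower among 33 tested, 5 and 5 adjusted over the list alone (median -0.18, adjusted p = 0.446). NKT2 genes had Epas1 (0.64, adjusted p = 0.0295) higher and the cytokine gene Il13 (-1.17, adjusted p = 0.0247) and Cd4 lower among 16, 3 and 2 adjusted over the list alone (median -0.06, adjusted p = 0.601). NKT17 genes had Sox13 and 5830411N06Rik higher and Ccr6 lower among 24, with the same counts adjusted over the list alone (median -0.16, adjusted p = 0.572). Cytokine genes had Ccl3 (5.01, adjusted p = 0.0157, from 6 and 0 counts in the WT replicates) higher and Il13 lower among 28, 3 and 2 adjusted over the list alone (median -0.40, adjusted p = 0.0940), and that list was called lower without WT replicate 2 (2.63e-05). Interferon response genes had Usp18 (0.67, adjusted p = 0.0291) higher and Oasl2 (-0.60, adjusted p = 0.0311) lower among 30, 1 and 2 adjusted over the list alone (median -0.13, adjusted p = 0.0632). T cell receptor activation genes had Spry1 (1.60, adjusted p = 0.00457) higher and Egr1 lower among 32, 2 and 1 adjusted over the list alone (median -0.27, adjusted p = 0.601), and the list was called lower without WT replicate 2 (5.60e-20). T cell receptor constant and coreceptor genes had Cd247 (0.82, adjusted p = 0.00747) and Slamf6 (0.55, adjusted p = 0.0303) higher among 14, 2 higher and 1 lower adjusted over the list alone (median 0.05, adjusted p = 0.625).

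Polycomb and growth genes showed single changes. Bmi1, a gene of the companion complex PRC1, rose (1.05, adjusted p = 0.00396), as did the fetal growth regulator Hmga2 (1.60, adjusted p = 0.0114) and the inhibitor gene Cdkn1c (1.62, adjusted p = 0.0141). Developmental regulators had 10 of 64 members tested, with 2 higher and 0 lower, 5 and 2 adjusted over the list alone (median 0.46, adjusted p = 0.169), and were called higher without WT replicate 2 (0.0371). Chromatin modifiers had 1 higher and 1 lower of 24, 1 and 4 adjusted over the list alone (median -0.15, adjusted p = 0.0838). Only Ezh2 was called among 11 PRC2 genes, also adjusted over the list alone (median -0.07, adjusted p = 0.446). Of 7 cell cycle inhibitor genes Cdkn1c alone was called, 1 higher and 1 lower adjusted over the list alone, with a median (-0.02) below and a mean (0.13) and test above 0 (adjusted p = 0.625), the median being 0.02 with library size scaling. Proliferation genes had 0 calls of 42 by edgeR, 0 adjusted over the list alone (median -0.06, adjusted p = 0.446). They summed to 7474 CPM in WT replicate 1 and 10547 in WT replicate 2, and were called lower as a list without WT replicate 1 (9.71e-11) and higher without WT replicate 2 (0.00320).

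Metabolic and stress lists stayed uncalled, each with 0 members called by edgeR and 0 adjusted over the list alone. Apoptosis genes (25 tested) had a median of -0.01 and adjusted p = 0.446, cholesterol genes (20) of 0.07 and 0.534, glycolysis genes (22) of 0.03 and 0.446, and heat shock genes (11) of -0.03 and 0.932, the last called lower without WT replicate 2 (0.00192). Scaled by library size, the medians of the apoptosis and heat shock genes were 0.04 and 0.02. Immature thymocyte genes (26) had only Lef1 called, likewise adjusted over the list alone (median -0.19, adjusted p = 0.623), and were called lower as a list without Ezh2-KO replicate 1 (0.0424). Markers of other cells gave Krt18 (2.94, adjusted p = 0.0261) higher among 5 thymic epithelium genes (adjusted p = 0.446) and Capg (-0.60, adjusted p = 0.0182) lower among 10 regulatory T cell genes (adjusted p = 0.932), with 1 higher in the former and 2 higher and 2 lower in the latter adjusted over the list alone. Erythroid markers (6 tested) had a median of 2.53 (adjusted p = 0.446) and summed to 37.5 CPM in Ezh2-KO replicate 1, 1.26 in Ezh2-KO replicate 2 and 2.43 and 2.75 in the WT replicates. They were called higher as a list without Ezh2-KO replicate 2 (adjusted p = 8.78e-20) and leaned lower without replicate 1 (0.0523). B cell (8), dendritic (11) and myeloid (10) markers had medians of -0.13, 0.05 and -0.16 with adjusted p of 0.446, 0.645 and 0.625, and 0, 1 and 0 genes adjusted over the list alone, the myeloid markers being called lower without Ezh2-KO replicate 1 (0.0490). Xist was the only tested gene of the sex-linked list (-0.71, adjusted p = 0.0514).

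**Figure D2:**
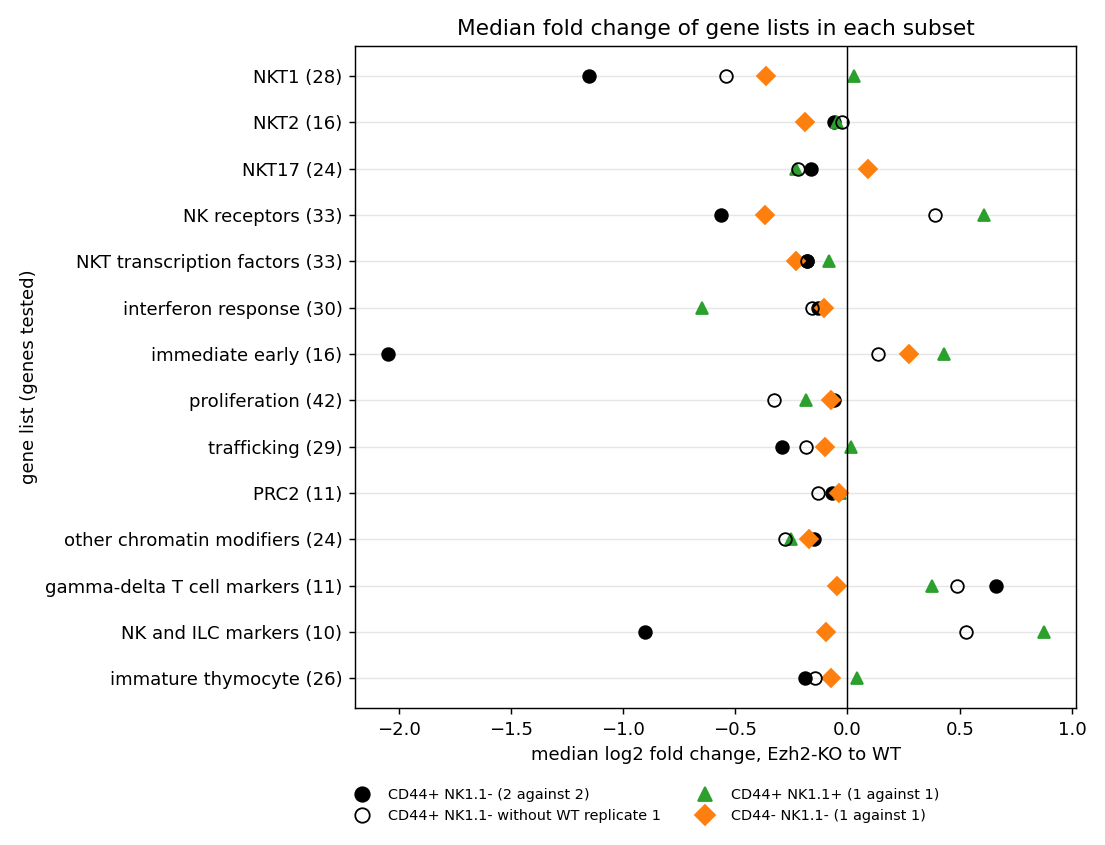
Median log2 fold change, Ezh2-KO to WT (x axis), of 14 gene lists (y axis, with the number of genes tested), in CD44+ NK1.1- cells with 2 against 2 libraries (black), the same without WT replicate 1 (open circles), CD44+ NK1.1+ (green triangles) and CD44- NK1.1- cells (orange diamonds, each 1 against 1 library). Immediate early genes moved from -2.05 to 0.13 and NKT1 genes from -1.15 to -0.54 without WT replicate 1.

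What Ezh2 loss changes in common to the 3 subsets was asked by fitting genotype beside subset over all 8 libraries. Mef2c rose by 5.50 (SE 0.25, adjusted p = 8.67e-05) and Eomes by 5.66 (SE 0.38, adjusted p = 0.000730). Grb10 (5.66, adjusted p = 0.000730), Nrn1 (4.36, adjusted p = 0.0116), Neo1 (3.75, adjusted p = 0.00162), Shtn1, a gene of nerve fibre growth (3.41, adjusted p = 0.000648), the NK receptor gene Klra8 (3.55, adjusted p = 0.00896) and Epha3 (5.70, adjusted p = 0.0157) completed the 8 largest rises. 9530036M11Rik changed by -2.77 (SE 0.14, adjusted p = 8.67e-05) and Rsrp1, an arginine and serine rich protein gene (gene identifier 27981, chromosome 4, 134923625 to 134927370), by -1.49 (SE 0.08, adjusted p = 8.67e-05). Cd4 (-1.36, adjusted p = 0.00193), Slc22a3 (-1.87, adjusted p = 0.00849), Igsf23 (-1.83, adjusted p = 0.0197), Dtx1 (-1.73, adjusted p = 0.00469), the iron carrier gene Trf (-1.39, adjusted p = 0.00841) and Dennd5a (-1.37, adjusted p = 0.00371) fell too. The naming rule allows no overlap between genotypes within a subset. Each of these genes therefore went the same way in all 4 Ezh2-KO libraries against the WT libraries of their subset. The Epha3 call ended without Ezh2-KO CD44+ NK1.1- replicate 1 or 2, WT CD44+ NK1.1- replicate 2 or either CD44+ NK1.1+ library (adjusted p up to 0.0623).

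Over the 3 subsets 1561 of 13794 genes differed, 887 higher and 674 lower, with 3707 at an unadjusted p under 0.05 and 487 and 80 over 2-fold. With library size scaling the split was 1044 higher and 490 lower. Leaving out a library gave 2794 calls without WT CD44+ NK1.1- replicate 1, where the split turned to 1273 higher and 1521 lower, 998 without WT replicate 2, 578 and 489 without Ezh2-KO replicates 1 and 2, 947 and 944 without the WT and Ezh2-KO CD44+ NK1.1+ libraries, and 1244 and 1213 without the WT and Ezh2-KO CD44- NK1.1- libraries. Tbx21 fell (-0.96, adjusted p = 0.0371), but that call ended without any of 6 libraries. They were WT replicates 1 (adjusted p = 0.133) and 2 (0.0990), Ezh2-KO replicates 1 (0.123) and 2 (0.123), and the WT (0.102) and Ezh2-KO (0.102) CD44- NK1.1- libraries. Il2rb (-0.81, adjusted p = 0.0501), Cd44 (-0.40, adjusted p = 0.0810), Zbtb16 (-0.07, adjusted p = 0.789), Gata3 (-0.15, adjusted p = 0.164), Il4 (-0.56, adjusted p = 0.129), Ifng (-2.28, adjusted p = 0.404), Il17a (-1.17, adjusted p = 0.567), Klrb1c (-1.003, adjusted p = 0.329) and Cdkn2a (-0.27, adjusted p = 0.473) were not called.

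Interferon response genes were lower over the 3 subsets, these being genes that cells switch on after interferon. Oasl2 (-0.83, adjusted p = 0.00333), Oasl1 (-0.69, adjusted p = 0.0457), Rsad2 (-0.53, adjusted p = 0.0132), Oas3 (-0.49, adjusted p = 0.0229), Ifit3 (-0.46, adjusted p = 0.00689), Cmpk2 (-0.40, adjusted p = 0.0369) and Ddx58 (-0.28, adjusted p = 0.0251) fell. Of 30 tested genes 0 rose and 7 fell, or 2 and 11 adjusted over the list alone. The median was -0.23 (camera adjusted p = 0.000306, and adjusted p = 0.908 with an estimated correlation), and it was -0.12 without the WT or the Ezh2-KO CD44+ NK1.1+ library. Chromatin modifiers were lower as well, with a median of -0.26 (camera adjusted p = 0.0142, and adjusted p = 0.766 with an estimated correlation), and were the only list here that fry called to move on balance in 1 direction (adjusted p = 0.00687). Bmi1 (0.82, adjusted p = 0.00351) rose, and among the genes that fell were the Polycomb gene Cbx8, the DNA demethylation genes Tet1 (-0.49, adjusted p = 0.0219), Tet2 and Tet3 (-0.37, adjusted p = 0.00745), Dnmt3b, Kmt2a and Kdm6a. In all there were 1 higher and 8 lower of 24, or 2 and 12 adjusted over the list alone.

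Gamma-delta markers were called higher in the fit over the 3 subsets, with a median of 0.52 (camera adjusted p = 0.00188, and adjusted p = 0.908 with an estimated correlation), although in CD44- NK1.1- cells their median was -0.05 (camera adjusted p = 0.643). 5830411N06Rik (0.92, adjusted p = 0.000450), Etv5 (0.52, adjusted p = 0.00967), Trgc1 (0.51, adjusted p = 0.0157) and Trgc2 (0.69, adjusted p = 0.0125) rose and Blk (-0.37, adjusted p = 0.0461) fell among 11, with 7 and 1 adjusted over the list alone. NKT1 genes were lower in this fit, with a median of -0.58 (camera adjusted p = 0.0103, and adjusted p = 0.908 with an estimated correlation), although in CD44+ NK1.1+ cells their median was 0.03. In the fit over the 3 subsets only Tbx21, Id2 (-0.43, adjusted p = 0.0141) and Cxcr3 (-0.49, adjusted p = 0.0389) fell and Ccl4 (1.37, adjusted p = 0.0131) rose among 28. Adjusted over the list alone, 1 rose and 4 fell, and the median was -0.26 without WT CD44+ NK1.1- replicate 1 and -0.98 without either CD44+ NK1.1+ library. Erythroid markers were higher, with a median of 4.10 (camera adjusted p = 0.0477, and adjusted p = 0.908 with an estimated correlation). Their haemoglobin gene Hbb-bs (4.37, adjusted p = 0.0488) was called, or 4 of 6 adjusted over the list alone, and haemoglobin paralogs may share reads. Their sum was 102 CPM in the Ezh2-KO CD44+ NK1.1+ library and 39.9 in the Ezh2-KO CD44- NK1.1- library, against 2.03 and 1.75 in WT, but Ezh2-KO CD44+ NK1.1- replicate 2, at 1.26 CPM, lay below the WT replicates of its subset (2.43 and 2.75). Among single genes of the uncalled lists, the integrin genes Itga4 (0.999, adjusted p = 0.000883) and Itgb1 (0.82, adjusted p = 0.000885), the cytokine genes Ccl3 (4.28, adjusted p = 0.00222) and Il21 (1.63, adjusted p = 0.00864) and Lin28b, a fetal regulator (3.96, adjusted p = 0.00712), rose. Ccr6 (-2.17, adjusted p = 0.00685), Itgae (-1.01, adjusted p = 0.00461), Ccr8 (-0.92, adjusted p = 0.00191), Il13 (-1.22, adjusted p = 0.00626) and the regulator gene Lhx2 (-1.84, adjusted p = 0.00713) fell. In CD44- NK1.1- cells Ccr6 had 1 count in WT and 2 in Ezh2-KO, so its fall rests on the CD44+ libraries.

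In CD44+ NK1.1+ cells, the late stage, the same question rested on 1 library per genotype, with the spread borrowed from the replicated groups. Eomes stood at 0.820 CPM in WT and 72.2 in Ezh2-KO, a change of 6.45 (SE 0.24, adjusted p = 0.00112), and Epha3 at 0.386 and 40.7, a change of 6.70 (SE 0.41, adjusted p = 0.00468). Arhgap24 rose by 5.04 (adjusted p = 0.00153) and the adhesion gene Chl1 by 3.83 (adjusted p = 0.0221). Cd4 stood at 175 CPM in WT and 45.1 in Ezh2-KO, a change of -1.96 (SE 0.14, adjusted p = 0.00786), and Il4, the cytokine gene typical of NKT2 cells, at 6.99 and 2.16, a change of -1.69 (SE 0.20, adjusted p = 0.0302). Igsf23 (-2.73, adjusted p = 0.0187), 9530036M11Rik (-2.28, adjusted p = 0.0169) and Fibcd1 (-2.19, adjusted p = 0.0169) fell, as did Thy1, a T cell surface gene (-1.29, adjusted p = 0.0239). Sox13 (2.32, adjusted p = 0.00468) and the integrin gene Itga4 (1.26, adjusted p = 0.0259) rose.

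EdgeR called 131 genes in CD44+ NK1.1+ cells, 109 higher and 22 lower, with 1394 at an unadjusted p under 0.05, and DESeq2 called 197, 136 higher and 61 lower. The count was 25 and 27 without Ezh2-KO CD44+ NK1.1- replicates 1 and 2 and 2434 and 2435 without WT replicates 1 and 2, as these libraries set the spread. Without either WT replicate fewer calls were higher (1181 and 1187) than lower (1253 and 1248). Of 18 named calls 5 stayed without either Ezh2-KO replicate, those of Epha3, Eomes, Arhgap24, Cd4 and Sox13. Tbx21 (378 CPM in WT, 356 in Ezh2-KO; -0.09, adjusted p = 0.958), Il2rb (-0.16, adjusted p = 0.958), Zbtb16 (0.49, adjusted p = 0.268), Cd44 (-0.34, adjusted p = 0.607), Gata3 (-0.06, adjusted p = 0.971), Ifng (0.14, adjusted p = 0.998), Klrb1c (0.34, adjusted p = 0.9799) and Cdkn2a (0.12, adjusted p = 0.987) were not called. Il17a had 2 counts in WT and 7 in Ezh2-KO (adjusted p = 0.967).

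Interferon response genes were lower in Ezh2-KO CD44+ NK1.1+ cells, with 29 of 30 below WT and a median of -0.65 (camera adjusted p = 1.48e-17, and adjusted p = 0.278 with an estimated correlation). Only Oasl2 (-1.09, adjusted p = 0.0440) was called over all genes, against 19 lower and 0 higher adjusted over the list alone. NK receptor genes were higher, with a median of 0.61 (camera adjusted p = 1.98e-05, and adjusted p = 0.809 with an estimated correlation). Klra4 (3.16, adjusted p = 0.0169), Klri1 (2.93, adjusted p = 0.0354) and Klrb1b (1.201, adjusted p = 0.0464) rose among 33, 5 adjusted over the list alone. NK or innate lymphoid markers were higher, with Eomes and Klra4 called, 2 of 10 adjusted over the list alone, and a median of 0.87 (camera adjusted p = 4.62e-06, and adjusted p = 0.741 with an estimated correlation). Gamma-delta markers were higher, with Sox13 and 5830411N06Rik (1.07, adjusted p = 0.0366) called, 5 of 11 adjusted over the list alone, and a median of 0.38 (camera adjusted p = 2.77e-06, and adjusted p = 0.741 with an estimated correlation). Developmental regulators were higher and proliferation genes lower with 0 members called by edgeR. Their medians were 0.44 (camera adjusted p = 0.00619, and adjusted p = 0.741 with an estimated correlation; 5 of 10 adjusted over the list alone) and -0.19 (camera adjusted p = 0.00538, and adjusted p = 0.809 with an estimated correlation; 0 of 42). Erythroid markers were higher in this library, with a median of 5.71 (camera adjusted p = 0.00528, and adjusted p = 0.806 with an estimated correlation) and 0 of 6 called. With genes at 0 to 3 counts set to their bound, the medians of the developmental and erythroid genes were 0.69 and 5.78. Beside these groups, immediate early genes summed to 1673 CPM in WT and 2019 in Ezh2-KO. With 1 library per genotype, camera at its preset correlation compares genes and does not measure spread between animals. The 2 WT CD44+ NK1.1- replicates, of the same genotype, differed by medians of 1.57 for NK receptor and -0.53 for proliferation genes. Both are larger than the shifts given here, whereas interferon response genes differed by 0.03 between those replicates.

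In CD44- NK1.1- cells, the early stage, the same question again rested on 1 library per genotype. Mef2c stood at 0.809 CPM in WT and 20.9 in Ezh2-KO, a change of 4.68 (SE 0.39, adjusted p = 0.0192). Chn1, a Rac regulator gene (4.02, adjusted p = 0.0192), the desmosome gene Dsp (3.38, adjusted p = 0.0188), Epha3 (3.31, adjusted p = 0.0232) and Eomes (3.18, adjusted p = 0.0206) rose too. 9530036M11Rik stood at 64.9 and 7.74 CPM, a change of -3.07 (SE 0.21, adjusted p = 0.0187). Slc22a3 (-2.84, adjusted p = 0.0187), Dtx1 (-1.92, adjusted p = 0.0198), Cd4 (-1.23, adjusted p = 0.0378) and the receptor variable gene Trbv1 (-2.08, adjusted p = 0.0187; reads may be shared among such segments) fell.

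EdgeR called 33 genes in CD44- NK1.1- cells, 25 higher and 8 lower, with 1247 at an unadjusted p under 0.05, and DESeq2 called 94, 49 higher and 45 lower. The count was 1 and 2 without Ezh2-KO CD44+ NK1.1- replicates 1 and 2 and 2484 and 2486 without WT replicates 1 and 2, of which fewer were higher (1147 and 1150) than lower (1337 and 1336). None of the 10 named calls stayed without Ezh2-KO replicate 1, nor without replicate 2. Tbx21 (40.4 CPM in WT, 17.2 in Ezh2-KO; -1.23, adjusted p = 0.0691), Il2rb (-0.78, adjusted p = 0.468), Zbtb16 (-0.39, adjusted p = 0.473), Gata3 (-0.10, adjusted p = 0.926), Il4 (-0.38, adjusted p = 0.585), Cd44 (0.07, adjusted p = 0.974), Klrb1c (-1.07, adjusted p = 0.891) and Cdkn2a (-1.11, adjusted p = 0.284) were not called, and Ifng and Il17a had at most 7 counts in either library. Erythroid markers were the only list called by camera, with a median of 4.73 (camera adjusted p = 0.0145, and adjusted p = 0.934 with an estimated correlation) and 0 of 6 members called, also adjusted over the list alone. That median was 4.78 with genes at 0 to 3 counts set to their bound. The limit on camera given for CD44+ NK1.1+ cells holds here too. NKT2 genes were called by fry alone, towards lower levels (median -0.19, fry adjusted p = 0.0486, camera adjusted p = 0.106).

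How far the genotype effect was shared between subsets was read from its sign. Of the 682 genes called in CD44+ NK1.1- cells, 652 (95.6%) had the same sign in CD44+ NK1.1+ and 612 (89.7%) in CD44- NK1.1- cells, against 66.8% and 64.1% of all tested genes. For genes called by DESeq2 the shares were 94.8% and 90.8%. Genes are not independent replicates, so these shares carry no test. Of the 131 genes called in CD44+ NK1.1+ cells 106 were also called in CD44+ NK1.1- cells with that sign, and of the 33 called in CD44- NK1.1- cells 31 were. Calls in the 3 subsets share the spread estimated from the CD44+ NK1.1- replicates, so overlaps of calls are not independent agreement. All 3 subsets called 21 genes alike, 18 higher and 3 lower. Epha3, Eomes, Mef2c, Grb10, Nrn1, Neo1, Shtn1, Chn1, Dsp, Arhgap24 and Tcf24 were among the higher, and Cd4, 9530036M11Rik and Rsrp1 were the lower.

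**Figure D3:**
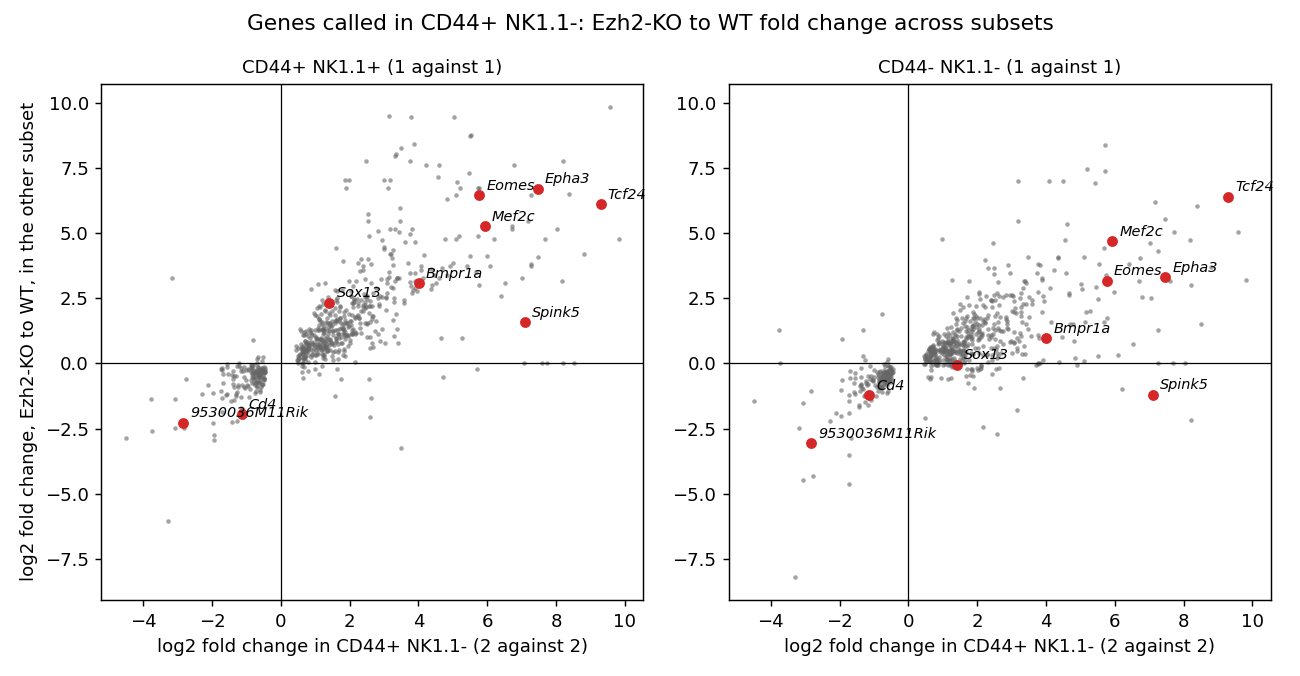
Log2 fold change, Ezh2-KO to WT, in CD44+ NK1.1- cells (x axis) against CD44+ NK1.1+ (left, y axis) and CD44- NK1.1- cells (right, y axis) for the 682 genes called in CD44+ NK1.1- cells (grey points), with named genes in red. Signs matched for 652 genes on the left and 612 on the right, and Spink5 was far from the others on the right.

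Whether the genotype effect differed between subsets was tested as an interaction. Between CD44+ NK1.1+ and CD44+ NK1.1- cells edgeR called 0 genes, with 519 at an unadjusted p under 0.05, while DESeq2 called 28. The differences were 1.198 (SE 0.19, adjusted p = 0.569) for Tbx21, -1.41 (SE 0.24, adjusted p = 0.589) for Il4, 0.67 (adjusted p = 0.894) for Zbtb16, 1.004 (adjusted p = 1) for Il2rb and 0.13 (adjusted p = 1) for Ezh2, so a change past the threshold in only 1 subset was not shown by edgeR with all libraries to differ for these genes. Of them DESeq2 called Tbx21 alone (adjusted p = 0.00223). Leaving out a WT replicate raised the count to 567 (replicate 1) and 2634 (replicate 2). Of 11 named genes 6 and 8 were then called, among them Tbx21, Il4, Zbtb16 and Il2rb in both cases, and leaving out either Ezh2-KO replicate gave 0.

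Between CD44- NK1.1- and CD44+ NK1.1- cells the genotype effect differed for 3 genes, all less positive in CD44- NK1.1- cells, with 648 at an unadjusted p under 0.05 and 28 by DESeq2. Spink5, a protease inhibitor gene (gene identifier 72432, chromosome 18, 43959545 to 44022487), differed by -8.29 (SE 0.35, adjusted p = 0.00401), the receptor gene Bmpr1a of the bone morphogenetic proteins (gene identifier 12166, chromosome 14, 34411061 to 34503336) by -3.05 (SE 0.23, adjusted p = 0.0403) and Trbv1 (gene identifier 621968, chromosome 6, 40891296 to 40891885) by -2.58 (SE 0.17, adjusted p = 0.0276). Spink5 had 2 and 3 counts in the WT and 348 and 337 in the Ezh2-KO CD44+ NK1.1- replicates, so that its change there is uncertain in size, and measured 0.110 ± 0.0275 and 15.9 ± 1.01 CPM in these cells and 33.6 and 14.7 in CD44- NK1.1- cells. Bmpr1a stood at 2.58 ± 0.241 and 41.6 ± 2.60, and at 22.1 and 42.9. For Ezh2 the difference was 0.16 (adjusted p = 0.992) and for Tbx21 0.05 (adjusted p = 0.996). Without Ezh2-KO replicate 1 or 2 only Spink5 stayed called (count 1 in each case), and the counts were 602 and 3063 without WT replicates 1 and 2.

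Which genes part CD44+ NK1.1- from CD44- NK1.1- cells, irrespective of genotype, was asked of 4 against 2 libraries. Cd44 itself, the gate gene, was higher in CD44+ cells (3.28, SE 0.13, adjusted p = 0.000506). Serpinb1a, a protease inhibitor gene of interleukin-17 producing T cells (gene identifier 66222, chromosome 13, 32842092 to 32853206), was higher by 5.68 (SE 0.27, adjusted p = 0.000928). Tbx21 was higher by 1.49 (SE 0.10, adjusted p = 0.00198), whereas Sox13 (-1.63, adjusted p = 0.000928) and Zbtb16 (-0.51, adjusted p = 0.0356) were lower. The other largest rises were in the NK receptor gene Klra1 (4.09, adjusted p = 0.00183), the fibrinogen-like gene Fgl2 (3.64, adjusted p = 0.0201), Pxdc1 (3.25, adjusted p = 0.000506), the cytokine receptor genes Il17re (3.07, adjusted p = 0.00188) and Il1r1 (2.91, adjusted p = 0.000506) and Samd3 (3.05, adjusted p = 0.00938). Falls were largest in the variable gene Trgv5 (-2.05), Setbp1 (-1.99), the relaxin gene Rln3 (-1.83), Tln2 (-1.69), H2-Eb2 (-1.57), Tspan9 (-1.44) and Pdzd2 (-1.37), with adjusted p between 0.00143 and 0.0169. Ccr6 had 921 counts in the CD44+ and 3 in the CD44- libraries, a ratio of 153 with a counting interval of 52.1 to 741.

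In all, 367 genes differed between these subsets, 220 higher in CD44+ cells and 147 lower, with 2124 at an unadjusted p under 0.05. Without Ezh2-KO replicates 1 and 2 the count was 83 and 90, and without WT replicates 1 and 2 it was 3461 and 4394. WT libraries alone gave 265 calls, 115 higher and 150 lower, and Ezh2-KO libraries alone 68, 64 higher and 4 lower. Of 42 named calls 19 and 18 stayed without Ezh2-KO replicates 1 and 2, and the calls of Tbx21, Cd44, Serpinb1a, Klra1, Pxdc1, Il17re, Il1r1, Sox13 and Ccr6 stayed in every setting tried. Il2rb (1.06, adjusted p = 0.0407) lost its call without either Ezh2-KO replicate (adjusted p up to 0.146). Ezh2 (0.12, adjusted p = 0.674), Gata3 (-0.08, adjusted p = 0.737), Il4 (-0.29, adjusted p = 0.235), Ifng (4.03, adjusted p = 0.543), Klrb1c (1.86, adjusted p = 0.371) and Cdkn2a (0.58, adjusted p = 0.174) were not called, and Il17a had 125 counts against 1 (adjusted p = 0.450).

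NKT17 genes were higher in CD44+ NK1.1- cells, 16 of 24 called higher and 1 lower, 18 and 1 adjusted over the list alone, with a median of 2.12 (camera adjusted p = 5.50e-37, and adjusted p = 0.246 with an estimated correlation). Trafficking genes gave 9 higher and 0 lower of 29, 18 and 1 adjusted over the list alone, with a median of 0.40 (camera adjusted p = 1.05e-13, and adjusted p = 0.246 with an estimated correlation). By fry, NKT17 and trafficking genes were on balance higher (adjusted p = 0.0146 and 0.0144) and NKT2 genes lower (0.0144). NK receptor genes had 7 of 33 higher, 15 adjusted over the list alone, and a median of 3.13 (camera adjusted p = 1.12e-33, and adjusted p = 0.505 with an estimated correlation). NKT1 genes had 6 of 28 higher, 12 adjusted over the list alone, and a median of 2.10 (camera adjusted p = 1.08e-25, and adjusted p = 0.505 with an estimated correlation). For NK or innate lymphoid markers these were 3 of 10, 5 adjusted over the list alone and 1.99 (camera adjusted p = 1.14e-08, and adjusted p = 0.505 with an estimated correlation). Proliferation genes had 1 of 42 higher, 3 adjusted over the list alone, and a median of 0.42 (camera adjusted p = 6.62e-08, and adjusted p = 0.749 with an estimated correlation). Cytokine genes had 2 of 28 higher, with 3 higher and 1 lower adjusted over the list alone, and a median of 0.68 (camera adjusted p = 0.000230, and adjusted p = 0.505 with an estimated correlation). Immediate early genes had 0 of 16 called, 1 adjusted over the list alone, and a median of 1.402 (camera adjusted p = 0.00397, and adjusted p = 0.761 with an estimated correlation), and their sum in WT replicate 1 enters this comparison too. So do the sums in that library of the NKT1 (4052 CPM against 2628 in WT replicate 2), NK receptor (1143 against 512) and NK or innate lymphoid genes (541 against 139). With genes at 0 to 3 counts set to their bound, the medians of the NK or innate lymphoid markers and the NK receptor genes were 1.43 and 3.12.

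Which genes part CD44+ NK1.1+ from CD44+ NK1.1- cells was asked of 2 against 4 libraries. Klrb1c, the gate gene, was higher in NK1.1+ cells (3.99, SE 0.57, adjusted p = 0.0251). Tbx21, the NKT1 factor, was higher by 2.31 (SE 0.09, adjusted p = 0.000282) and Il2rb by 2.47 (SE 0.16, adjusted p = 0.000688), whereas Il4 was lower (-2.69, SE 0.13, adjusted p = 0.000421) and so was Zbtb16 (-1.03, SE 0.09, adjusted p = 0.00109). Ezh2 was lower (-1.06, SE 0.11, adjusted p = 0.00179), with WT levels of 57.1 CPM in NK1.1+ and 125 ± 15.9 in NK1.1- cells. The largest rises were in the potassium channel gene Kcnj8 (5.53), the NK receptor genes Klra5 (5.11), Klri2 (5.06), Cd244a (5.004), Klrc1 (4.65) and Klrc2 (4.46), the adaptor gene Fcer1g (4.79) and Gzmb, a gene of cytotoxic granules (4.95), with adjusted p between 0.0194 and 0.0395. Complement gene Hc (-4.39), Il13 (-4.39), Tgm3 (-4.24), Akr1c18 (-4.11), Il21 (-4.09), Slc22a3 (-3.81), Igfbp4 (-3.78) and Nos1 (-3.62) fell furthest, with adjusted p between 0.000282 and 0.00402.

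Between these subsets 4479 genes differed, 2262 higher in NK1.1+ cells and 2217 lower, with 6237 at an unadjusted p under 0.05. WT libraries alone gave 1416 calls and Ezh2-KO libraries alone 2565. Leaving out Ezh2-KO replicate 1 or 2 gave 1627 and 1519, and leaving out WT replicate 1 or 2 gave 8586 and 7876. Of 107 named calls 81 and 83 stayed without Ezh2-KO replicates 1 and 2, and that of Klrb1c was among those lost (adjusted p up to 0.196). The survival gene Bcl2 (2.62, adjusted p = 0.00419), the perforin gene Prf1 (4.30, adjusted p = 0.000866), Cd44 (1.24, adjusted p = 0.000928) and Id2 (1.79, adjusted p = 0.000283) were higher, and the interleukin-6 receptor gene Il6ra (-3.51, adjusted p = 0.000282), Cdkn2a (-1.98, adjusted p = 0.00170) and Hmga2 (-4.26, adjusted p = 0.000718) were lower. Gata3 (-0.20, adjusted p = 0.121), Ifng (3.03, adjusted p = 0.171) and Il17a (-2.66, adjusted p = 0.335) were not called.

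NK receptor genes were higher in NK1.1+ cells, 28 of 33, or 32 adjusted over the list alone, with a median of 3.60 (camera adjusted p = 1.40e-26, and adjusted p = 0.574 with an estimated correlation). NKT1 genes were higher, 24 of 28, or 26 adjusted over the list alone, with a median of 3.38 (camera adjusted p = 5.14e-26, and adjusted p = 0.574 with an estimated correlation). NK or innate lymphoid markers followed with 8 of 10, or 9 adjusted over the list alone, and a median of 2.73 (camera adjusted p = 1.84e-08, and adjusted p = 0.574 with an estimated correlation). NKT2 genes were lower, 12 of 16 with 1 higher, the same adjusted over the list alone, and a median of -1.39 (camera adjusted p = 3.65e-13, and adjusted p = 0.434 with an estimated correlation). They were the only list here that fry called to move on balance in 1 direction (adjusted p = 0.00194). Proliferation genes were lower, 38 of 42 with 2 higher, or 39 and 2 adjusted over the list alone, and a median of -1.07 (camera adjusted p = 3.14e-16, and adjusted p = 0.576 with an estimated correlation). NKT17 genes had 11 lower and 2 higher of 24, or 13 and 2 adjusted over the list alone, and a median of -0.70 (camera adjusted p = 0.00197, and adjusted p = 0.574 with an estimated correlation).

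Smaller shifts between these subsets were called for 5 more lists. Immature thymocyte genes were lower, 9 of 26, or 10 lower and 1 higher adjusted over the list alone (median -0.28, camera adjusted p = 0.00509, and adjusted p = 0.574 with an estimated correlation). Among trafficking genes 15 rose and 8 fell of 29, or 17 and 9 adjusted over the list alone (median 0.59, camera adjusted p = 0.00509, and adjusted p = 0.574 with an estimated correlation). Apoptosis genes were higher, 7 of 25, the same adjusted over the list alone (median 0.23, camera adjusted p = 0.0385, and adjusted p = 0.574 with an estimated correlation). Developmental regulators had 4 lower and 1 higher of 10, or 5 and 1 adjusted over the list alone (median -0.70, camera adjusted p = 0.0385, and adjusted p = 0.576 with an estimated correlation), with a median of -0.44 once genes at 0 to 3 counts were set to their bound. B cell markers had Cd22 (3.77, adjusted p = 0.00101), Ighm (1.16, adjusted p = 0.000644) and Ighd (3.09, adjusted p = 0.00252) higher and Cd74 (-0.74, adjusted p = 0.0273) lower of 8, the same adjusted over the list alone (median 0.56, camera adjusted p = 0.0151, and adjusted p = 0.574 with an estimated correlation). Across the 6 comparisons with lists, none of the 36 camera calls held with an estimated correlation, the lowest adjusted p being 0.246.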

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

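The tests on cells of another subset, on handling, on scaling, on GC content or gene length and on splits even in every subset were chosen only after the result was seen, whereas those on all splits of the libraries, on the WT spread and on Trdv genes were not.

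For 3 genes the genotype effect in CD44- NK1.1- cells differed from that in CD44+ NK1.1- cells by a test of the difference itself. Spink5, a protease inhibitor gene, differed by -8.29 on the log2 scale (SE 0.35, adjusted p = 0.00401), with a change of 7.10 in CD44+ NK1.1- cells, where the WT replicates had 2 and 3 counts and its size is uncertain, and -1.19 in CD44- NK1.1- cells. Bmpr1a, a receptor gene for bone morphogenetic proteins, differed by -3.05 (SE 0.23, adjusted p = 0.0403), with changes of 4.01 and 0.96. Trbv1, a receptor variable gene, differed by -2.58 (SE 0.17, adjusted p = 0.0276), with changes of 0.50 and -2.08. In each case the WT CD44- NK1.1- library stood apart, at 33.6 CPM for Spink5 against at most 0.129 in the other WT libraries, 22.1 against at most 4.73 for Bmpr1a and 406 against at most 92.1 for Trbv1. Without Ezh2-KO CD44+ NK1.1- replicate 1 or 2 only Spink5 stayed called, and with robust=FALSE Bmpr1a was not. No explanation was tested for these genes, each of which rests on 1 library per genotype in CD44- NK1.1- cells.

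The fit of genotype over the 3 subsets holds subset fixed, so only splits of the 8 libraries that part every subset evenly compare with the split by genotype. There are 12 of these, the split by genotype included, which are too few for a share under 0.05. The split by genotype was the 1 with as many called genes, 1561, and the highest of the others gave 0. Among all 34 splits into 4 and 4 that could be fitted, the set chosen before the data were seen, the highest of the others gave 2, but most of these are uneven within subsets.

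The first pattern is that WT CD44+ NK1.1- replicate 1 stood above replicate 2 in genes typical of CD44+ NK1.1+ cells and in immediate early genes, by medians of 1.29 on the log2 scale for NKT1, 1.57 for NK receptor and 3.22 for immediate early genes. If NK1.1+ cells were mixed into the library, 398 genes lower in NK1.1+ cells implied a share of 36.8% (interval 33.2 to 41.1). Genes higher there implied 18.6% (16.8 to 19.98), and 47 NKT1, NK receptor and NK or innate lymphoid genes among these 12.1% (10.1 to 13.8). Intervals above 0 were what a mixture predicts, and unlike shares what a further cause predicts. However, the genes were chosen partly by their level in replicate 2, which also enters the share. Chance highs and lows in replicate 2 can therefore raise both shares, by unlike amounts. The shares do not decide whether such cells were mixed in or were the whole cause. Immediate early genes would need a share of 581% of cells at the level of the WT CD44+ NK1.1+ library. That excludes NK1.1+ cells at that level as their source, but not NK1.1+ cells with a higher level in this sample. A sort on NK1.1 would remove most NK1.1+ cells. For the immediate early genes handling or stimulation during isolation cannot be told apart from a difference between animals, since heat shock genes lay at the 68.2nd percentile of random lists with a median of 0.06, although among them Hspa1a had 344 counts in replicate 1 and 9 in replicate 2, and Dnajb1 3101 and 2083, and handling can raise immediate early genes alone. T cell receptor activation genes, some of them immediate early genes, were also higher in replicate 1 (median 0.31, percentile 99.99), and proliferation genes were lower (-0.53, percentile 0). Immature thymocyte genes had a higher median there (0.28, percentile 99.88) but a lower sum, 2719 CPM against 2788 in replicate 2. These do not show whether a stimulus came before or during isolation. No biological explanation was tested, as the labels give nothing that parts the WT replicates.

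The second pattern is that more of the called genes were higher than lower in Ezh2-KO CD44+ NK1.1- cells, 522 against 160. A bias by GC content or gene length cannot be told apart from a real excess, as 75.9% of 615 calls were higher with that trend removed and 76.5% of 648 before, but the trend was centred at a median of 0, which holds the scaling, and a version run first without centring, which moved the median fold by -0.10, gave 52.8% of 852. Neither can scaling for the overall share, since other scalings gave 76.1% at the lowest but a shift of every fold by -0.1 gave 60.2%, and the same holds for called genes over 2-fold different, where that shift left 82.7% of 475 higher but is too small to turn the sign of such genes. The spread between the WT replicates also keeps the overall share open, as 61.5% (interval 57.3 to 65.6) of 551 genes over 2-fold different, called or not, were higher, and of 157 uncalled lower ones 126 had WT replicates over 2-fold apart. The share depended on the method too, as the DESeq2 test had 58.7% of 653 calls higher. It also moved widely, both ways, with 1 CD44+ NK1.1- replicate left out. Loss of Ezh2, whose complex keeps genes silent, stays open as an untested explanation.

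The third pattern is that gamma-delta T cell markers were higher in Ezh2-KO CD44+ NK1.1- cells. Gamma-delta T cells mixed into those libraries are a candidate source. Trdv genes, variable genes of the delta chain, had 185 counts in Ezh2-KO and 36 in WT, a ratio of 5.41 (interval 3.77 to 7.96) over 5 genes. Most of the rise came from Trdv2-1 (4 and 1 counts in the WT, 30 and 38 in the Ezh2-KO replicates) and Trdv2-2 (7 and 6, 40 and 45). Trdv5 had 9 and 1 against 14 and 14, Trdv1 had 1 and 2 against 1 and 3, and Trdv4 fell from 4 and 1 to 0 and 0. Trdc had 1480 counts in Ezh2-KO and 379 in WT, a ratio of 4.11 (3.67 to 4.61). Trgv genes, high in WT too, rose by a ratio of 1.61 from 11593 to 17723 counts, and among them Trgv5 rose more, from 101 and 131 counts in the WT replicates to 929 and 930 in the Ezh2-KO replicates. Trdc was higher in the Ezh2-KO than in the WT library of CD44+ NK1.1+ cells (580 counts against 218), as were Trdv2-2 (58 against 8) and Trdv2-1 (33 against 1), but not in CD44- NK1.1- cells (Trdc 160 against 194). These single libraries do not decide on a mixture. A change of these genes within NKT cells after loss of Ezh2 stays open as untested, since of the 12 markers Sox13, Blk, Maf, Etv5 and 5830411N06Rik are also in the NKT lists and a sort on the NKT receptor would remove gamma-delta cells.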

How the results depend on the processing

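Only the settings without 5 gene lists were tests chosen after the result was seen. All settings set out beforehand could be run. With DESeq2 size factors every count of called genes stayed within 1.5 times its value, as did those for Ezh2-KO against WT in CD44+ NK1.1- cells and over the 3 subsets with no filter, a filter at 1 CPM, library size scaling, limma-voom, the DESeq2 test and robust=FALSE. Without the 5 lists these counts were 713 and 1602.

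Against a fold of 1.5 the counts were 290 in CD44+ NK1.1- cells and 264 over the 3 subsets, a stricter test by construction, and the mean of 3 genotype effects gave 951 for the latter. With no filter CD44+ NK1.1+ cells gave 233 calls, CD44- NK1.1- cells 87, and the differences of the genotype effect 1 (CD44+ NK1.1+) and 24 (CD44- NK1.1-). DESeq2 gave 197, 94, 28 and 28 for these. Ezh2-KO libraries alone gave 68 between CD44+ NK1.1- and CD44- NK1.1- cells, and between CD44+ NK1.1+ and CD44+ NK1.1- cells WT libraries alone gave 1416 and Ezh2-KO libraries alone 2565. The cause was not tested. The counts for single genotypes came from contrasts in the fit of all 8 libraries, so they share 1 spread and scaling. Single genotypes have fewer libraries, but that does not account for the unlike counts, as WT and Ezh2-KO hold equal numbers of libraries.

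Leaving out single libraries moved the counts both ways. The range was 101 to 5792 in CD44+ NK1.1- cells, 489 to 2794 over the 3 subsets, 25 to 2435 in CD44+ NK1.1+ cells, 1 to 2486 in CD44- NK1.1- cells, 83 to 4394 between CD44+ NK1.1- and CD44- NK1.1- cells, 1519 to 8586 between CD44+ NK1.1+ and CD44+ NK1.1- cells, and 0 to 2634 and 1 to 3063 for the differences of the genotype effect in CD44+ NK1.1+ and CD44- NK1.1- cells. In the model of 6 groups, low counts came without an Ezh2-KO replicate and high ones without a WT replicate. The construction shows why, as the spread then rests on the WT pair or on the closer Ezh2-KO pair alone.

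For named genes, 3747 values kept direction and side of the threshold, 596 lost their call, 92 gained one and 13 changed sign, all of these for genes uncalled in the main setting. In CD44+ NK1.1- cells Cdkn2a was 0.024 with library size scaling, and over the 3 subsets Il17a was 0.039 with limma-voom. Without single libraries Cdkn2a went from -0.11 to 0.059 and Il17a from -2.63 to 2.33 in CD44+ NK1.1- cells. Over the 3 subsets the ranges were -0.25 to 0.040 for Zbtb16, -1.86 to 1.85 for Il17a and -0.37 to 0.0096 for Cdkn2a. For the difference of the genotype effect in CD44+ NK1.1+ cells they were -0.0099 to 0.25 for Ezh2 and -0.52 to 4.44 for Il17a. For that in CD44- NK1.1- cells they were -0.056 to 0.15 for Tbx21 and -0.49 to 1.18 for Klrb1c. Called gene lists in CD44+ NK1.1- cells kept direction and call in 14 cases with a library left out. Lists over all comparisons lost the call in 37 cases, 36 with an estimated correlation and 1 for trafficking genes without Ezh2-KO replicate 2. Immediate early genes reversed once, without WT CD44+ NK1.1- replicate 1 (adjusted p = 0.416), and its lowest adjusted p was 1.31e-114 without WT replicate 2.

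Depth limits genes near 3 counts, such as Il17a, Ifng in CD44- NK1.1- cells and Tcf24 in WT.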

Other observations

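No test in this part was chosen after the result was seen, as it reports values only.

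The first principal component held 52.0% of the variance and parted the CD44+ NK1.1+ libraries from the others. On the second, with 20.7%, all 4 WT libraries lay on the positive and all 4 Ezh2-KO libraries on the negative side. The perforin gene Prf1 went from 6.70 ± 3.40 CPM in WT CD44+ NK1.1- to 83.6 in WT CD44+ NK1.1+ cells, and from 2.43 ± 0.0635 to 76.0 in Ezh2-KO. Eomes, in contrast, stood at 0.820 CPM in WT CD44+ NK1.1+ cells and 72.2 in Ezh2-KO.

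Xist, the transcript of the silent X chromosome, was present in all 8 libraries, the sex-linked list summing to between 141 and 287 CPM. Haemoglobin and other erythroid genes summed to 37.5, 1.26, 102 and 39.9 CPM in Ezh2-KO CD44+ NK1.1- replicates 1 and 2, CD44+ NK1.1+ and CD44- NK1.1- libraries, and to at most 2.75 CPM in WT.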
